A study of Homo sapiens with 18 samples.

How the data were processed

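HEK293 is an established human embryonic kidney cell line. In polysome profiling a cytoplasmic lysate is spun through a sucrose gradient, which separates mRNAs by the number of ribosomes they carry. Per the labels, cells received DMSO vehicle or 100 µM minocycline, a tetracycline antibiotic, for 12 h. Gradients were divided into monosome, light polysome and heavy polysome pools, and each pool was sequenced as single-end reads of 75 nt. The series has 18 libraries. The table used here holds the 9 libraries of the vehicle control, 3 replicates of each fraction. The 9 libraries of minocycline-treated cells are not analysed here, so the planned comparison of minocycline with vehicle was not made.

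Per the submitters' processing notes, reads were assigned to genes with featureCounts on GRCh38; the aligner, the counting options and whether strand was used are not given in the sources used here. The per-library signal in the table deposited by the authors is a gene count divided by 1 size factor per library. Dividing each column by its smallest step recovered whole reads for 100% of the values in every library, at a tolerance of 0.01 reads. The size factors lay within 1.71% of those given by the median-of-ratios method on the recovered reads. Each fraction was thereby scaled to the same typical gene, so percentages and ribosome loads are relative between genes and say nothing of how much RNA each fraction held. Per the labels, ERCC spike-ins were added to the fractions, and they are not used here. The deposited percentage of a gene in a fraction is its share of the summed normalized count over the 3 fractions with the same replicate number, and was recomputed to within 5.5e-08. The authors' deposited mean ribosome load (MRL) is a score, and it was recomputed to within 7.83e-10 as the mean percentages weighted by 1 for monosome, 2.5 for light and 6 for heavy polysomes. The weights stand for ribosomes per mRNA and were solved from the table. The authors' deposited polysome enrichment on a log2 scale has no stated formula and was set against MRL by rank. The deposited log2 fold change and its adjusted p-value carry no stated contrast or test. In the authors' deposited table, 233 rows without a gene symbol list a fold change of 0 with an adjusted p-value of 0; these were left out of every count taken from those columns. The deposited strict class of a gene requires 1 fraction to lead in all 3 replicates with at least 50% and a margin of 10 points, and a summed normalized count of at least 100. This rule and a relaxed one with 45% gave the deposited class of 13661 of 13661 genes.

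The design had been written for counts or percentages. Because the values turned out to be normalized counts, fractions were compared with limma on log2(normalized count + 1), and count tests on the recovered reads served as alternatives. Fold changes are on that scale, which understates the change of low genes. Genes were kept with a mean of at least 10 recovered reads over the 9 libraries and with reads in each gradient, which left 12720 of 13661 genes and removed 941. Gene models and coding lengths came from GENCODE release 29 on GRCh38, where 13658 identifiers matched, and 12715 of the genes kept had a coding length. Two-sided tests used a Benjamini-Hochberg adjusted p of 0.05. For MRL, each gradient gave 1 value per gene, and limma's moderated test (trend) asked whether log2 MRL minus the median gene of that gradient differed from 0 over the 3 gradients. For fractions, the 9 libraries were fitted together with fraction as the only term. Contrasts of light polysome with monosome and of heavy with light polysome were added after the data were seen. Gene lists were compared with all other genes by camera at a preset correlation of 0.01, and again with a correlation estimated from the data, for lists with at least 5 genes kept. Per-gene counts within a list are given over all genes tested and adjusted over the list alone.

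Lists, the planned comparisons and the rule for naming genes were fixed before the data were examined. The light over monosome and heavy over light contrasts were added later, and limma was chosen once the unit of the values was seen. In each per-gene test the rule took the 10 highest and 10 lowest genes past the threshold, with the same direction in every replicate, reads in every library and a normalized count in the upper 6360 genes. It added the 2 highest and 2 lowest members by MRL of each list with at least 5 genes, ATF4, GAPDH, ACTB, EEF1A1 and the mitochondrially encoded mRNAs. Not every gene the rule selects is reported here. The fixed lists covered the large and small cytosolic ribosomal subunits, other TOP mRNAs, initiation factors, tRNA synthetases, stress-response and ATF4 target mRNAs, polyamine, selenoprotein, iron and cholesterol genes. They also covered mitochondrial, proteasome, glycolysis, histone, chaperone, matrix, cytoskeletal, splicing, cell cycle, replication, nucleolar, nuclear pore, immediate early and interferon genes, and markers of other cell types. The lists of snoRNA host transcripts, long noncoding RNAs and small noncoding RNAs had 0 genes in the table and gave no result.

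The labels give each library a batch number equal to its replicate number, so the numbers were taken to pair the fractions of 1 gradient. As a check, deviations of same-numbered libraries from their fraction means correlated between -0.54 and 0.39, with 4 of 9 correlations over 0.1. Of the 9 libraries, 2 correlated best with their own number in both other fractions. The fit without the replicate block is the main one and the fit with it an alternative. Per the series' design text, replicates are biological.

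Recovered reads per library ranged from 13447139 to 24441159. Intervals on shares of reads are 95% Wilson intervals, none wider than 0.0266 percentage points to either side, and cover counting error only. The procedures were tested on simulated counts for the 12720 genes with an assumed dispersion of 0.05 and 100 genes changed at each size. For heavy over monosome, limma recovered 59% of the genes at a log2 change of 1 and 100% at 2, and called 9 unchanged genes. For MRL, 44% and 100% were recovered and 20 unchanged genes were called. In the list test a list of 20 genes shifted by -0.3 was called, and 0 of 200 unshifted lists were. Simulated genes were drawn independently, while the estimated correlation within the real small-subunit ribosomal protein list was 0.965. The simulation therefore does not show how often camera at the preset correlation calls an unshifted list of correlated genes. Its recovery rates hold only for the assumed dispersion.

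Alternatives covered pseudocounts of 0.1 and 5, edgeR and DESeq2 on recovered reads, no filter, the upper genes by abundance, other centring, other ribosome weights, other measures of load, the replicate block and leaving out each replicate. Those chosen after the data were seen were the edgeR fits, the deposited percentages, leaving out single libraries, the relaxed class, the deposited transcript length, leaving out ribosomal protein and TOP mRNAs from the length relation, and leaving out each replicate there. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.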

Results

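The data describe where each mRNA of vehicle-treated HEK293 cells sat in a sucrose gradient: with a single ribosome (monosome), in light polysomes or in heavy polysomes. The 9 libraries formed 3 fractions with 3 biological replicates each. Monosome libraries held 16128888, 13447139 and 16145486 reads in replicates 1, 2 and 3. Light polysome libraries held 18948136, 16809945 and 19558832 reads, and heavy polysome libraries 17045699, 24441159 and 15103945. Of 13661 genes in the table, 12720 were kept. Libraries of minocycline-treated cells were not analysed here, so every comparison is within the vehicle control.

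Mitochondrially encoded mRNAs and cytosolic ribosomal protein mRNAs made up much of the monosome libraries. The 13 mitochondrial mRNAs took 26.0%, 3.87% and 19.5% of the monosome reads in replicates 1, 2 and 3. Their share was 3.08%, 0.225% and 2.72% in light polysomes and 0.279%, 0.0996% and 0.288% in heavy polysomes. Ribosomal protein mRNAs took 38.5%, 54.1% and 33.9% of the monosome reads, 15.8%, 7.17% and 18.6% of the light polysome reads, and 7.61%, 5.44% and 11.3% of the heavy polysome reads. Counting error is small against the differences between replicates, with Wilson 95% intervals of at most 0.0266 percentage points to either side.

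**Figure D1:**
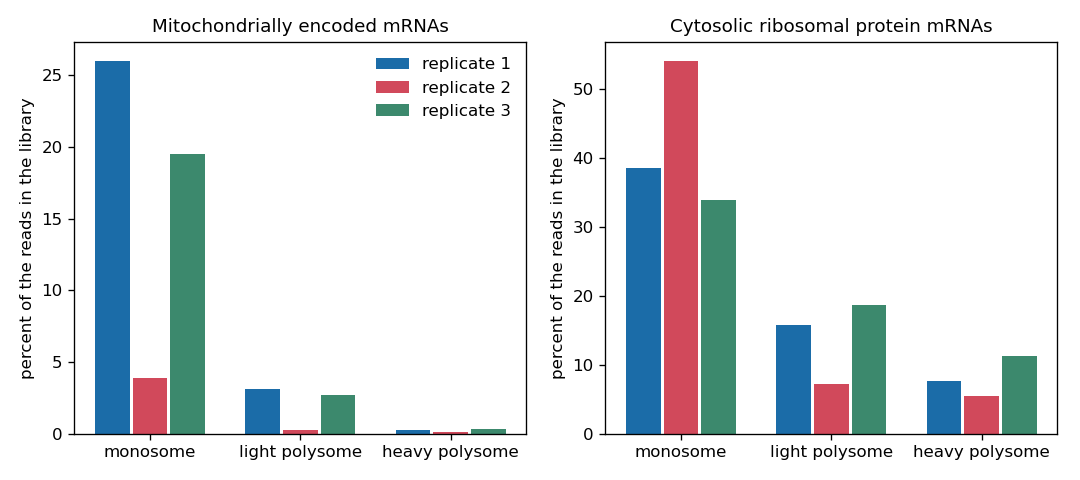
Percent of the reads of each control library (y axis) from mitochondrially encoded mRNAs (left) and cytosolic ribosomal protein mRNAs (right), by fraction (x axis); each bar is 1 library, coloured by replicate. Replicate 2 had the lowest mitochondrial share in each fraction (3.87%, 0.225% and 0.0996%) and the highest ribosomal protein share in the monosome fraction (54.1%).

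Libraries of a fraction correlated across genes on the log2 scale, with 1 library apart. Light polysome libraries 1 and 3 correlated at r = 0.985. Light polysome library 2 correlated on average at 0.894 with those libraries and at 0.940 with the 3 heavy polysome libraries. The correlation of MRL across genes was 0.869 between replicates 1 and 3, 0.724 between 1 and 2 and 0.640 between 2 and 3 (Pearson r; genes are not independent replicates).

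**Figure D2:**
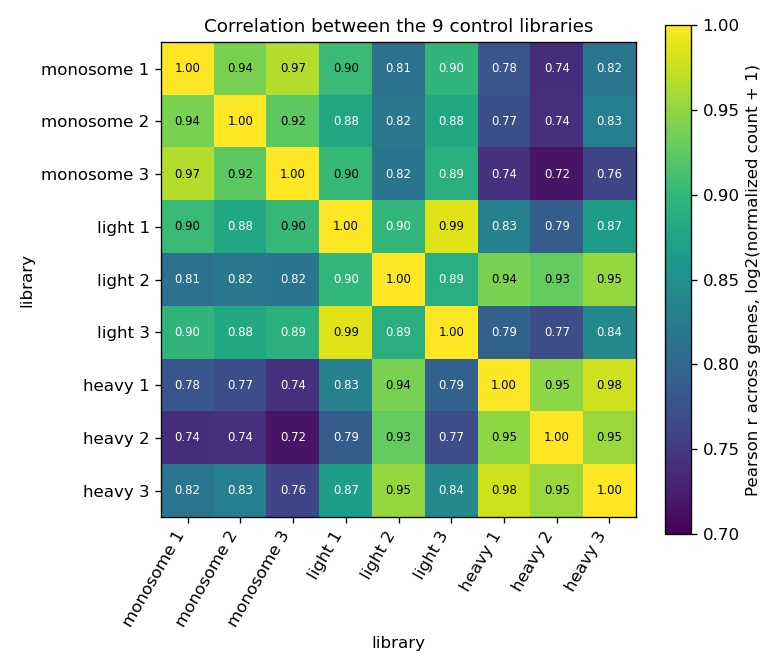
Pearson r across genes of log2(normalized count + 1) between the 9 control libraries (both axes); colour and printed number give r. Light library 2 has r of 0.93 to 0.95 with the heavy libraries and of 0.89 to 0.90 with light libraries 1 and 3.

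The first question was which mRNAs had a higher or lower MRL than the typical mRNA. MRL had a median over genes of 3.17 ± 0.01 (SD, n = 3 gradients). Scaling each fraction to the same typical gene largely fixes this median. Neither its size nor its small SD therefore measures the cells or the agreement of the gradients. RBM42, which encodes an RNA-binding protein (ENSG00000126254, GRCh38 chromosome 19, 35629030 to 35637686), had an MRL of 5.15 ± 0.37 (SD, n = 3) and 79.6% ± 8.8 of its signal in heavy polysomes. NUDC, for a dynein-associated protein (ENSG00000090273, chromosome 1, 26900238 to 26946862), had 5.13 ± 0.52, and ANP32A 5.13 ± 0.51. RTF1, a transcription elongation factor, had 5.11 ± 0.27. EIF4A3, a core protein of the exon junction complex, had 5.09 ± 0.28, and the pyruvate dehydrogenase subunit PDHA1 5.03 ± 0.29. The heparan sulfate proteoglycan SDC2, the proteasome subunit PSMD3, the ribosome assembly factor LTV1 and the splicing factor PRPF19 lay between 4.98 and 5.02. At the other end MT-CO2, a cytochrome c oxidase subunit (mitochondrial genome, 7586 to 8269), had an MRL of 1.07 ± 0.04 with 96.9% ± 1.8 in monosomes. MT-ATP6 also had 1.07, MT-ND4 and MT-ND1 had 1.08, MT-CO3 1.09, MT-ND2 1.10 and MT-ND3 1.14. These mitochondrial mRNAs are translated inside the organelle, so their MRL gives a place in the gradient and not a load of cytosolic ribosomes. SELENOW, a small selenoprotein (ENSG00000178980, chromosome 19, 47778572 to 47784686), had 1.09 ± 0.01, RPL41 1.10 ± 0.06 and SMIM27 1.12 ± 0.03.

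Against the median gene, 2798 genes had a higher MRL and 3139 a lower one, and 6783 did not pass limma's moderated test. RBM42 lay 0.70 above the median gene on the log2 scale (SE 0.07, adjusted p = 0.000356 by limma, higher in 3 of 3 gradients). MT-CO2 lay at -1.57 (SE 0.08, adjusted p = 7.69e-05, lower in 3 of 3). Centred on the mean gene in place of the median gene, the split was 3537 higher and 2713 lower. Without replicate 1 the total of 5937 calls became 3422, with 1258 higher, and without replicate 3 there were 1838 higher.

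Translation machinery mRNAs were tested as 6 fixed lists. The list of large-subunit ribosomal proteins had a median MRL of 1.55 ± 0.34 (SD, n = 3), and 48 of its 48 genes were lower (48 adjusted over the list alone). The small-subunit list had 1.47 ± 0.30, with 33 of 33 lower (33 adjusted over the list alone). Replicate 2, where these mRNAs took 54.1% of the monosome reads, had the lowest medians, 1.22 and 1.18. RPL8 (2.30 ± 0.92) and RPL3 (2.17 ± 0.49) were the highest of the large subunit and FAU (2.19 ± 0.48) of the small one, and RPL36A (1.24 ± 0.08) and RPS29 (1.16 ± 0.09) were low. Many ribosomal protein genes have near-identical processed pseudogenes, and how the authors' counting treated shared reads is not given, so single values are uncertain. Other mRNAs with a terminal oligopyrimidine (TOP) start had 2.14 ± 0.28, with 16 of 21 lower (16 adjusted over the list alone). The translation elongation factor EEF1A1 had 1.54 ± 0.15 and TPT1 1.37 ± 0.31, while NPM1 (3.42 ± 0.87) and VIM (3.20 ± 0.35) did not pass. Initiation factors had 3.64 ± 0.12, with 12 of 27 higher and 2 lower (13 and 3 adjusted over the list alone). EIF3B reached 4.80 ± 0.17, and EIF4E (2.51 ± 0.43) and EIF1 (2.47 ± 0.33) were lower. That list leaves out EIF3E, EIF3F, EIF3H, EIF3K, EIF3L, EIF4B and EIF4A2, which were placed among the other TOP mRNAs. In a test added later, the 53 genes kept with EIF symbols had 3.31 ± 0.06. Of these, 16 were higher and 16 lower (adjusted p = 0.795 by camera at the preset correlation). Of 20 tRNA synthetases, 10 were higher and 1 lower (11 and 1 adjusted over the list alone), with WARS1 at 4.79 ± 0.51 and QARS1 at 2.00 ± 0.11. Ribosome biogenesis genes had 3.91 ± 0.12, with 15 of 23 higher (15 adjusted over the list alone), DKC1 at 4.58 ± 0.51. By camera with the preset correlation these lists passed at an adjusted p of 1.52e-18 for the large subunit, 6.06e-16 for the small subunit, 1.08e-05 for other TOP mRNAs, 0.00565 for initiation factors, 0.000727 for synthetases and 0.000724 for biogenesis. In that order the adjusted p = 0.375, 0.375, 0.414, 0.375, 0.315 and 0.315 with an estimated correlation, so none passed.

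Mitochondrial gene groups were tested as 4 fixed lists, each against all other genes. Mitochondrially encoded mRNAs, which are translated inside the organelle, had a median MRL of 1.10 ± 0.02, with 13 of 13 lower (13 adjusted over the list alone); their share of monosome reads was 3.87% in replicate 2 against 26.0% and 19.5%. MT-ND6 (1.55 ± 0.30) and MT-ND5 (1.52 ± 0.44) were the highest. Mitochondrial genes such as MT-ATP8 and MT-ATP6 overlap, and how reads in the overlap were counted is not given, so their separate values are uncertain. Nuclear-encoded subunits of oxidative phosphorylation had 2.82 ± 0.39, with 32 of 74 lower and 8 higher (32 and 10 adjusted over the list alone). Their medians were 2.87, 2.41 and 3.19 in replicates 1, 2 and 3, and without replicate 2 the list did not pass (adjusted p = 0.39). UQCRC1 had 4.92 ± 0.44 and ATP5F1B 4.46 ± 0.41, against 1.52 ± 0.03 for ATP5MF and 1.51 ± 0.05 for NDUFC1. Mitochondrial ribosomal proteins had 3.26 ± 0.46, with 18 of 75 higher and 16 lower (18 and 16 adjusted over the list alone), and the list did not pass (adjusted p = 0.644 by camera); its median lay above and its mean below the typical gene. Without replicate 2 that list passed (adjusted p = 0.034). Mitochondrial chaperones and proteases had 3.86 ± 0.16, with 8 of 12 higher (8 adjusted over the list alone), TRAP1 at 4.61 ± 0.25. The adjusted p by camera was 5.44e-11 for the encoded mRNAs, 0.0165 for oxidative phosphorylation and 0.00461 for the chaperones. In that order the adjusted p = 0.315, 0.728 and 0.334 with an estimated correlation.

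Proteasome subunits and glycolytic enzymes had the highest loads among the lists tested by the mean over replicates, but not in replicate 2 (3.52 and 3.84, against 4.12 for matrix proteins). Proteasome subunits had a median MRL of 4.24 ± 0.64, with 22 of 31 higher (26 adjusted over the list alone), PSMD3 at 5.02 ± 0.46 and PSMD14 at 4.76 ± 0.51. Glycolytic enzymes had 4.18 ± 0.30, with 10 of 16 higher (11 adjusted over the list alone); PGAM1 had 4.84 ± 0.84 and PGK1 4.79 ± 0.20. GAPDH had 2.97 ± 1.20, did not pass, and ranged from 1.77 in replicate 2 to 4.17 in replicate 3. Cytosolic chaperones had 3.98 ± 0.09, with 13 of 22 higher and 1 lower (14 and 2 adjusted over the list alone), HSP90AA1 at 4.68 ± 0.28 and the small heat shock protein HSPB1 at 1.68 ± 0.13. Endoplasmic reticulum chaperones had 3.81 ± 0.06, with 13 of 23 higher and 1 lower (15 and 1 adjusted over the list alone), PDIA3 at 4.89 ± 0.23 and EDEM1 at 2.56 ± 0.26. Cell cycle regulators had 4.03 ± 0.09, with 14 of 25 higher and 1 lower (14 and 1 adjusted over the list alone), CDC20 at 4.57 ± 0.40. DNA replication genes had 3.76 ± 0.20, with 10 of 23 higher and 1 lower (10 and 1 adjusted over the list alone), PCNA at 4.91 ± 0.25 and DUT at 2.53 ± 0.04. Cholesterol synthesis genes had 3.81 ± 0.26, with 10 of 20 higher (11 adjusted over the list alone), NSDHL at 4.54 ± 0.43. In that order the adjusted p by camera was 9.94e-08, 0.000387, 0.00319, 0.000259, 0.000727, 0.000727 and 0.000727. With an estimated correlation the adjusted p = 0.414, 0.352, 0.334, 0.315, 0.348, 0.315 and 0.375.

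Splicing and structural groups had median MRLs above that of the typical gene. SR splicing factors had 3.88 ± 0.31 (6 of 12 higher, 6 adjusted over the list alone), SRSF1 at 4.51 ± 0.31. Core spliceosome proteins had 3.74 ± 0.22 (11 of 24 higher and 5 lower, 11 and 5 adjusted over the list alone), with SNRPB at 4.86 ± 0.65 and SNRPG at 1.86 ± 0.03. Matrix and large secreted proteins had 3.66 ± 0.41 (6 of 21 higher, 6 adjusted over the list alone), SPARC at 4.79 ± 0.71. Cytoskeletal proteins had 3.63 ± 0.16 (9 of 26 higher and 2 lower, 9 and 2 adjusted over the list alone). ACTB, the cytoplasmic actin, had 4.48 ± 1.00, while the thymosins TMSB10 (1.57 ± 0.16) and TMSB4X (1.54 ± 0.09) were lower. Nuclear pore proteins and karyopherins had 3.55 ± 0.38 (4 of 21 higher, 3 adjusted over the list alone), NUP88 at 3.98 ± 0.38. Neuronal genes that embryonic kidney lines express had 3.99 ± 0.29 (4 of 7 higher, 5 adjusted over the list alone), UCHL1 at 4.66 ± 0.42. In that order the adjusted p by camera was 0.0101, 0.0421, 0.0147, 0.0287, 0.0155 and 0.0185. With an estimated correlation the adjusted p = 0.414, 0.414, 0.499, 0.352, 0.557 and 0.375. Matrix (3.36, 4.12 and 3.49) and nuclear pore (3.30, 3.99 and 3.36) medians were highest in replicate 2, and without it neither list passed (adjusted p = 0.126 and 0.206). Cytoskeletal proteins did not pass without replicate 3 (0.104), nor the spliceosome without replicate 1 (0.0525) or 3 (0.0828).

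Several further groups lay below the typical gene. The list tests did not match genes on coding length. Genes with short coding sequences had low median MRLs, 1.99 for at most 300 nt and 2.54 for 301 to 600 nt. Stress-response mRNAs with upstream open reading frames had a median MRL of 2.44 ± 0.19, with 5 of 9 lower (5 adjusted over the list alone). ATF4, the transcription factor of that response, had 1.91 ± 0.26 with 63.6% ± 4.0 in monosomes, and DDIT3 had 1.55 ± 0.11. Target genes of ATF4 lay above the typical gene at 3.81 ± 0.15, with 11 of 21 higher and 1 lower (11 and 1 adjusted over the list alone); PSAT1 had 4.70 ± 0.53 and NUPR1 1.63 ± 0.30. Polyamine genes had 2.54 ± 0.10 (5 of 9 lower, 5 adjusted over the list alone), SAT1 at 1.56 ± 0.08. Selenoproteins had 2.63 ± 0.03 (8 of 17 lower and 2 higher, 8 and 2 adjusted over the list alone), from 1.09 for SELENOW to 4.39 ± 0.36 for TXNRD1. Replication-dependent histones had 2.09 ± 0.07 (12 of 13 lower, 13 adjusted over the list alone), H4C8 at 1.48 ± 0.08. Histone values rest on low counts, with a median normalized count of 39.3 against 377 for the genes kept. In the order stress response, ATF4 targets, polyamine, selenoproteins and histones, the adjusted p by camera was 0.0112, 0.000727, 0.0291, 0.0132 and 1.32e-05. With an estimated correlation the adjusted p = 0.414, 0.352, 0.352, 0.348 and 0.315. Polyamine genes did not pass without replicate 2 (adjusted p = 0.0545). Immediate early genes (2.86 ± 0.18, 9 of 24 lower and 3 higher, 9 and 3 adjusted over the list alone) did not pass as a list (adjusted p = 0.142), although MYC had 4.06 ± 0.21 and EGR1 1.75 ± 0.42. Iron genes (2.64 ± 0.21, 4 of 8 lower and 2 higher, 4 and 2 adjusted over the list alone) did not pass (adjusted p = 0.297, or 0.0425 without replicate 3), with FTH1 at 1.79 ± 0.65 and ACO1 at 3.98 ± 0.29. Interferon-stimulated genes (3.12 ± 0.70, 2 of 7 higher and 1 lower, 2 and 1 adjusted over the list alone) did not pass either (adjusted p = 0.88); the test pointed up, while the median and mean deviation were -0.09 and -0.05. Tested on the share of signal in light plus heavy polysomes in place of MRL, 12 of the lists that passed no longer did, and immediate early genes did. The 12 were tRNA synthetases, stress-response mRNAs, polyamine genes, selenoproteins, oxidative phosphorylation, mitochondrial chaperones, cytosolic chaperones, matrix, cytoskeleton, core spliceosome, nuclear pore and neuronal genes. Among the upper 6360 genes by abundance, the cytoskeleton, core spliceosome and nuclear pore lists no longer passed, and matrix, neuronal and histone lists were too short to be tested.

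**Figure D3:**
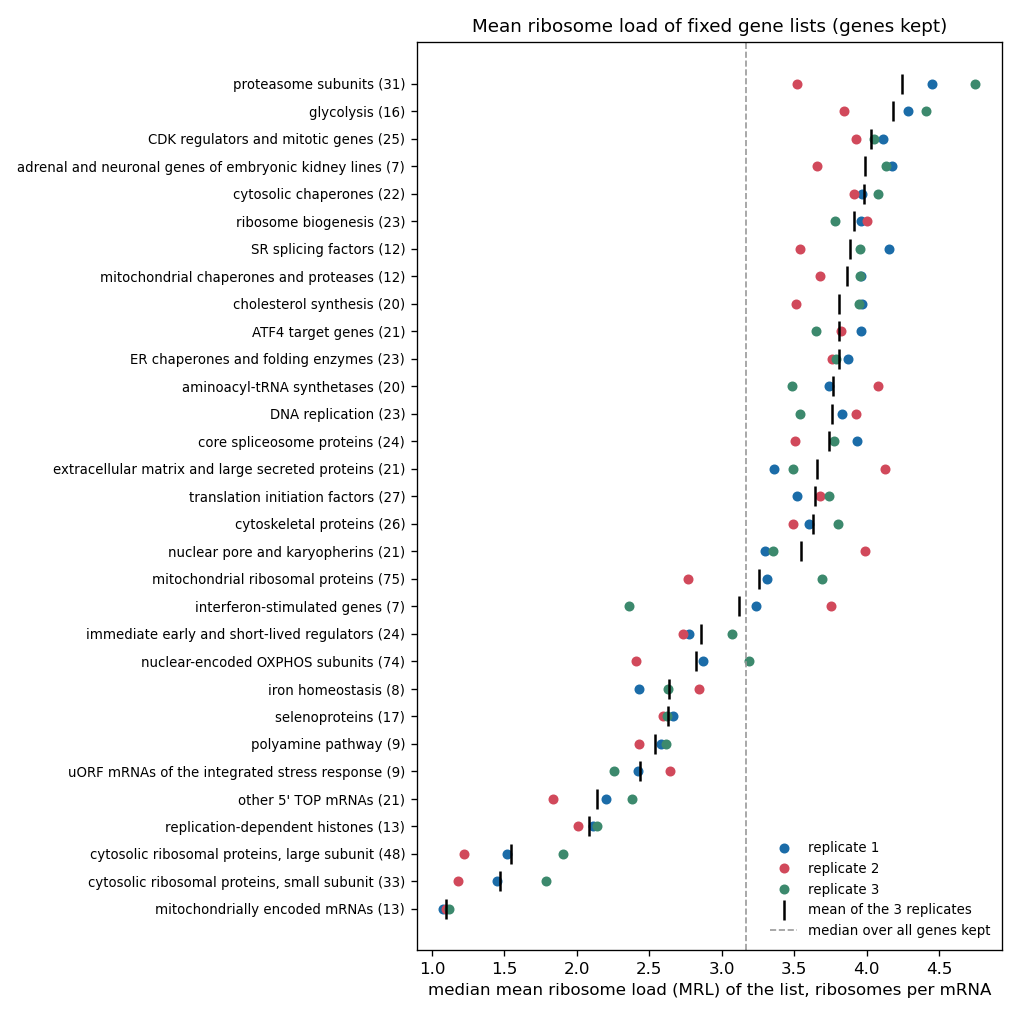
Median MRL (x axis, ribosomes per mRNA under the authors' weights) of each fixed list (y axis, number of genes kept in brackets); dots are the 3 replicate gradients, the black mark their mean and the dashed line the median over all genes kept. By the mean, lists run from mitochondrially encoded mRNAs at 1.10 to proteasome subunits at 4.24.

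The next comparison set heavy polysomes against monosomes gene by gene. HMGN5, a nucleosome-binding protein, had the largest change toward heavy polysomes among the abundant genes, 4.13 on the log2 scale (SE 0.57, adjusted p = 0.000135 by limma, higher in 3 of 3 replicates). RTF1 followed at 3.76, the tetraspanin CD81 at 3.67, ANP32A at 3.66 and the chromatin protein HMGB2 at 3.63. NUDC had 3.44, HNRNPAB 3.41, the peptide-processing enzyme CPE 3.40, the replication clamp PCNA 3.35 and the nonsense-mediated decay factor UPF3B 3.33. Toward monosomes, MT-CO2 had -7.74 (SE 1.22, adjusted p = 0.000292), MT-ATP6 -7.65, MT-ND4 -7.55, MT-CO3 -7.33, MT-ND1 -7.19 and MT-ND2 -7.09. MT-ND3 had -6.88, SELENOW -6.82, MT-CO1 -6.82 and MT-ATP8 -6.81. ATF4 had -2.89 (SE 0.58, adjusted p = 0.00136) and EEF1A1 -3.52 (SE 0.71, adjusted p = 0.00135). ACTB had 2.06 (SE 0.67, adjusted p = 0.0202), and GAPDH had -0.60 (SE 0.64, adjusted p = 0.459) and was not called.

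Of the 12720 genes, 3145 were higher in heavy polysomes, 3101 were higher in monosomes and 6474 did not pass. All 81 ribosomal protein genes and all 13 mitochondrially encoded genes were on the monosome side (48, 33 and 13 adjusted over the list alone), with list medians of -3.63, -4.09 and -6.88 for the large subunit, small subunit and mitochondrial genes. Toward heavy polysomes were 24 of 31 proteasome subunits (25 adjusted over the list alone, median 1.74) and 10 of 16 glycolytic enzymes (10 adjusted over the list alone, median 1.52). The median change over all genes kept was 0.13 with limma, 0.10 with edgeR's TMM scaling and 0.51 in the authors' deposited table. No list tested turned sign between these scalings except the interferon-stimulated genes, with medians of 0.39 by limma and -0.36 by edgeR. Without replicate 1 the 6246 calls became 3137, and without replicate 3 they became 3948. In the authors' deposited table, whose contrast is not stated, 4404 genes had a positive and 2454 a negative fold change at an adjusted p-value under 0.05; its fold changes correlated with those computed here at r = 0.988 across genes and lay higher by a median of 0.40.

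The share of signal in light polysomes had a median of 37.8% for genes with a coding sequence of at most 300 nt, 28.3% for 1501 to 3000 nt and 42.3% above 6000 nt. Against monosomes, TENM1, a large transmembrane teneurin, had a change of 3.78 and 79.7% ± 8.5 of its signal in light polysomes, and AKAP9, a large centrosomal scaffold, 3.47 and 69.8% ± 16.2. The short mRNA of TCEAL9 had 2.85, and ONECUT2, a transcription factor, 2.80. Lower in light polysomes than in monosomes were RPL41 (-5.26), RANBP6 (-4.83), SELENOW (-4.81) and the histone mRNA processing factor LSM10 (-4.73). In total 1077 genes were higher in light polysomes, 1303 were higher in monosomes and 10340 did not pass; 47 of 48 large-subunit and 31 of 33 small-subunit ribosomal protein genes were among the lower (47 and 33 adjusted over the list alone). The total of 2380 calls was 562 without replicate 1, 4507 without replicate 2 and 936 without replicate 3.

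Among abundant genes higher in heavy than in light polysomes were RBM42 (2.91), NUDC (2.83), the respiratory chain subunit UQCRC1 (2.76) and the citrate cycle subunit IDH3B (2.70). Higher in light polysomes were the thymosin TMSB15A (-3.13), the oxidative phosphorylation subunits NDUFB1 (-2.99) and ATP5F1E (-2.98), MRPL33 (-2.90) and HMGN2 (-2.89). TMSB15A, TMSB15B and TMSB15C are near-identical copies, so their values are uncertain. Of the fixed lists, 23 of 31 proteasome subunits, 13 of 22 cytosolic chaperones and 9 of 16 glycolytic enzymes were higher in heavy polysomes. Adjusted over each list alone these counts were 27, 16 and 13, with 1 chaperone higher in light polysomes. Higher in light polysomes were 6 of 9 polyamine genes, 28 of 74 oxidative phosphorylation subunits, 9 of 17 selenoproteins and 8 of 13 histones. Adjusted over each list alone these counts were 6, 33, 10 and 8. In heavy polysomes, 11 oxidative phosphorylation subunits and 3 selenoproteins were higher. In total 1869 genes were higher in heavy and 2228 in light polysomes. This comparison rested on single libraries: the 4097 calls became 6423 without light library 2 and 2295 without heavy library 2. Without replicate 2 there were 7651 calls. Without replicate 1 limma called 0 genes (2490 at an unadjusted p under 0.05, 132 by edgeR), and without replicate 3 it called 1 (3100 unadjusted, 1052 by edgeR).

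The authors' deposited classes name the fraction that holds most of a gene's signal. Of 13661 genes, 1549 were in the strict monosome class, 501 in the light polysome class and 1654 in the heavy polysome class, and 9957 were unassigned. The strict monosome class held 46 of 48 large-subunit and 33 of 33 small-subunit ribosomal protein genes and 12 of 13 mitochondrially encoded genes. The strict heavy class held 18 of 31 proteasome subunits and 12 of 22 cytosolic chaperones. The authors' deposited polysome enrichment ranked the genes kept as MRL did, with a Spearman rho of 0.983 across genes.

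Coding length bounds how many ribosomes an mRNA can hold, and MRL was set against it. Genes with a coding sequence of at most 300 nt had a median MRL of 1.99 ± 0.11 (SD, n = 3, 252 genes), those of 301 to 600 nt 2.54 ± 0.13, those of 601 to 900 nt 3.09 ± 0.22 and those of 901 to 1500 nt 3.26 ± 0.13. For 3001 to 6000 nt the medians were 3.23, 3.76 and 3.16 in replicates 1, 2 and 3. Across genes, Spearman's rho of mean MRL with coding length was 0.25, and it was 0.159, 0.477 and 0.0902 within replicates 1, 2 and 3. Without replicate 2 it was 0.127, and with the deposited transcript length in place of coding length 0.0262. The deposited length is, by its name, a minimum for each gene and covers the transcript, so it is not a like measure.

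**Figure D4:**
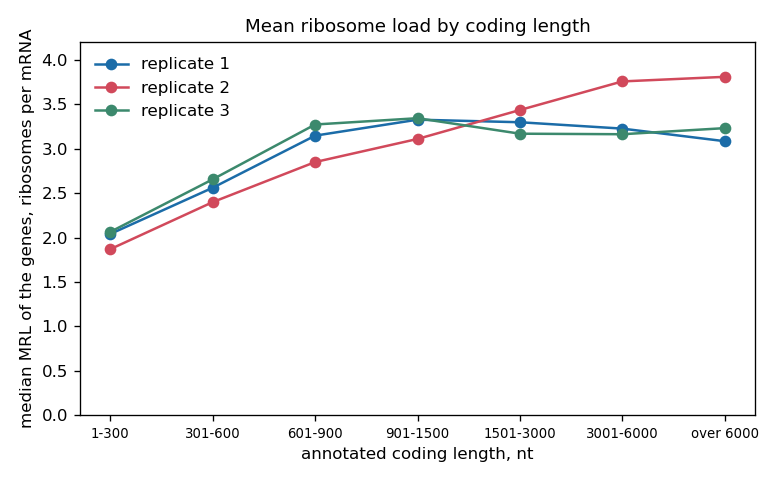
Median MRL of the genes in each coding length class (y axis, ribosomes per mRNA under the authors' weights) against annotated coding length in nt (x axis); each line is 1 replicate gradient. All 3 rise from about 2 in the shortest class (2.04, 1.87 and 2.06) up to 901 to 1500 nt. Replicates 1 and 3 are highest there (3.33 and 3.35) and lower in longer classes. Replicate 2 rises further and reaches 3.81 in the longest class against 3.09 and 3.23.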

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

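The light over monosome and heavy over light contrasts, edgeR fits, deposited percentages, single libraries left out, the relaxed class and the changes to the length relation other than the filters were chosen after the data were seen. The 200 alternative values of MRL and the 300 of heavy over monosome covered the 10 highest and 10 lowest genes by each test. All kept direction and call. Those genes were picked as the most extreme past the threshold with 1 direction in every replicate, so that outcome was largely set in advance. Other named genes were not rerun. No list called turned sign, but the uncalled interferon-stimulated list had a heavy over monosome median of 0.39 by limma and -0.36 by edgeR. The side with more calls turned in 2 of 10 alternatives for MRL (centred on the mean, and without replicate 2) and in 9 of 15 for heavy over monosome, DESeq2 and both edgeR fits among them. It turned in 1 of 15 for light over monosome and 1 of 15 for heavy over light. The turn for heavy over light, without replicate 3, rests on 1 call against 0. Without replicate 1 both sides had 0 calls, so neither had more. Single lists kept theirs in 254 of 306 alternatives; 49 lost the threshold, of which 27 with an estimated correlation, and 3 gained it. With replicate block the heavy over monosome count was 6274 (3152 higher, 3122 lower), light over monosome 2424 and heavy over light 4302; the pairing moved no count by over 1.5 times. For MRL no fit without the pairing was run. Each of its values combines the 3 fractions with the same replicate number, so every MRL result rests on that pairing.

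Leaving out each replicate gave 3422 to 7264 MRL calls (1258 to 3698 higher, 2164 to 3566 lower). It gave 3137 to 7814 for heavy over monosome (1271 to 3996 higher, 1866 to 3818 lower) and 562 to 4507 for light over monosome (149 to 2202 higher, 413 to 2305 lower). For heavy over light it gave 0 to 7651 (0 to 3806 higher, 0 to 3845 lower) by limma, with 2490 genes at an unadjusted p under 0.05 and 132 by edgeR where limma called 0. The rho with coding length was 0.127 to 0.33. The upper genes by abundance gave 3545 MRL calls (1665 higher, 1880 lower), from fewer genes tested. Deposited percentages gave 4049 calls for light over monosome (1960 higher, 2089 lower) and 3003 higher for heavy over light. Rescaled percentages gave 4062 (2050 higher, 2012 lower), and 3352 lower for heavy over light. Without light library 2 heavy over light had 6423 calls (3137 higher), and without heavy library 2 it had 2295 (1071 higher, 1224 lower). By list, 27 passed (18 higher, 9 lower); with an estimated correlation limma's camera called 0 (3 at an unadjusted p under 0.05, adjusted p from 0.315 to 0.941), and on the light plus heavy share 16 passed (10 higher), 12 lost and 1 gained. A margin of 10 points left 1696 of 3300 genes dominated by light polysomes, and the relaxed class held 810 light genes. Deposited transcript length, by its name a minimum for each gene, gave a rho of 0.0262. For these the cause was not tested, and the estimated correlation is taken up below. Fewer genes or samples entered some of them, yet the per-gene calls rose without replicate 2 and without light library 2.

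With 3 gradients, the estimated correlation and its p-values by camera rest on 2 residual degrees of freedom. Failure to pass there was nearly set in advance and does not show that correlation within lists made the calls. Estimated correlations for endoplasmic reticulum chaperones, DNA replication and ribosome biogenesis were -0.032, -0.023 and -0.005, below the preset 0.01. Yet their unadjusted p by camera rose from 5.85e-05, 0.000328 and 0.00021 to 0.0472, 0.058 and 0.0548. ERCC scaling, the minocycline comparison and random lists for means were not run.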

Other observations

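The symbol families and tests of swap, mitochondrial shift, less mitochondrial RNA, coding length and splits were chosen after related results had been seen. Families sharing a symbol root with at least 20 genes kept, 58 in all, were compared with the other genes by camera at the preset correlation, and 12 passed. Zinc finger genes named ZNF, mostly DNA-binding regulators, had a median MRL of 2.60 ± 0.16 (SD, n = 3), and 225 of 425 were lower and 8 higher (adjusted p = 3.8e-11 for the family). Their median coding length was 1755 nt. The ZBTB family, also zinc finger transcription factors, had 2.31 ± 0.07 (25 of 41 lower, 1 higher, adjusted p = 3.01e-06), and the ZDHHC palmitoyltransferases 2.36 ± 0.02 (12 of 21 lower, 2 higher, adjusted p = 0.0121). Small integral membrane proteins (SMIM) had 2.13 ± 0.06, with 21 of 22 lower (adjusted p = 1.34e-08) and a median coding length of 249 nt. The DDX helicases lay above the typical gene at 3.64 ± 0.25 (12 of 31 higher, adjusted p = 0.00846). With an estimated correlation 0 of the 58 families passed (2 at an unadjusted p under 0.05, lowest adjusted p = 0.91).

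Markers of other cell types were scarce: 3 haematopoietic, 1 hepatocyte and 3 fibroblast genes were kept, with median normalized counts of 69.2, 18.2 and 39.7, too few for a list test. The 233 rows without a symbol, which the authors' deposited table lists at a fold change of 0, had a median absolute log2 ratio of heavy over monosome means of 1.17.

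Light polysome library 2 lay nearer the heavy libraries than the other light libraries. A swap with heavy library 2 is argued against, since that library correlated with light 1 and 3 less than with heavy 1 and 3, by -0.172. Depth is argued against too: light 1 and 3 thinned to its reads stayed below its correlation with heavy 1 and 3, by -0.113. A gradient cut so that all 3 fractions hold longer polysomes was predicted to make library 2 rise with coding length in each. The lowest rho was -0.226, in monosomes (0.123 in light, 0.506 in heavy). That prediction need not hold for monosomes, since small polysomes added to that pool could come from short mRNAs. The test therefore cannot decide, and such a cut stays open. A light pool that alone took in heavier polysomes, or a mislabelled library from elsewhere, may also account for the place of light library 2. No biological explanation was tested.

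Mitochondrially encoded mRNAs had a low share of monosome library 2. A move to heavier fractions of that gradient is argued against, since their share there was at most 0.357 of the lowest share in replicates 1 and 3. Of 39 gene and fraction pairs, 36 were lowest in replicate 2. The 13 monosome pairs restate the pattern, and genes of 1 library do not vary independently. By a rule added after this count was seen, it decides nothing, so less mitochondrial RNA in all fractions of that gradient stays open. Lysis, and a difference between the cultures, may also be involved and were not tested.

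Cytosolic ribosomal protein mRNAs had a low MRL. Short coding length alone is argued against. The lowest of 10000 sets of other genes matched on coding length lay 0.708 above their median of 1.52, with 0 sets at or below it. Genes of a set were drawn independently, while the estimated correlations within the ribosomal protein lists were 0.923 and 0.965. The count of sets may therefore overstate the evidence. For sets matched on normalized count the lowest lay 0.916 above that median. However, 57 of 81 genes lie above every other gene used, and those sets reached a median count of 12492 against 64712. That test was set aside as void by a rule added after its result was seen, so abundance stays open. TOP regulation is a candidate explanation that was not tested, and reads shared with pseudogenes also stay open.

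For each fraction comparison the 6 libraries allow 10 splits, too few for a share under 0.05. Only 1 split, the real one, reached 6246 genes for heavy and monosome, 2380 for light and monosome, and 4097 for heavy and light, and the highest other split gave 0 genes by limma in each (802, 997 and 3370 at an unadjusted p under 0.05).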
